A study of Oryza sativa with 12 samples.

How the data were processed

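Transcript levels were measured in shoots and roots of rice seedlings of the cultivar IKP on dual-channel Agilent oligonucleotide arrays of 60-mer probes. Per the labels, seedlings 25 days old stood in hydroponic solution for 48 h with no added salt, with 200 mM NaCl or with 100 mM Na2SO4, and RNA came from 100 mg of pooled tissue, with 10 µg RNA per labelling. Each organ gave 3 direct comparisons: NaCl against control, Na2SO4 against control and Na2SO4 against NaCl. Each comparison was hybridised on 2 arrays, which are biological replicates per the labels, so the series held 12 arrays on 3 slides. Slide and position came from the scanner's records. Per the labels, the reference RNA carried the green dye and the treated RNA the red dye on each array.

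The deposited scanner files hold, per spot, the mean signal and the median local background of each channel as linear intensity, without normalization. They also hold a log10 ratio of red over green, which per the file headers follows background subtraction and dye normalization within the array. The authors' software was Agilent Feature Extraction, version 9.1 in the labels and 11.5.1.1 in the file headers. The deposited value table holds the same log10 ratios. It differed from the scanner files by at most 5e-10 on 10 arrays, and by up to 0.0049 and 0.005 on the root and shoot Na2SO4 against control arrays of replicates 1 and 2, whose scanner files write decimal commas and rounded values. No array was turned in the deposited table.

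Ratios were recomputed from the intensities. With limma 3.58.1 in R 4.3.3, signals were corrected by normexp with an offset of 50, turned to log2 of red over green, and normalized by loess within each array. Spots of 1 probe were averaged. A probe was kept in an organ where it was well above background, by the scanner's own call, in at least 1 channel on both arrays of at least 1 comparison. This left 30330 probes in shoots, 24467 in roots and 23904 in both. Each locus was represented by its probe of highest mean intensity, giving 22787 genes in shoots, 18796 in roots and 18309 in both organs.

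The files pair probes with rice locus identifiers and, for 2167 of 28314 loci, with an informative description. No identifier matched the reference table of gene symbols (0 of 33954 spots with a RefSeq accession and 0 loci), so the names are those of the files. Coordinates are those of the probes on the rice genome build IRGSP 5, per the file headers. Probes that match more than 1 locus (1331) were not named.

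Each comparison was tested with limma (lmFit and eBayes, two-sided) on the 6 arrays of its organ, with 1 coefficient per comparison and 3 residual degrees of freedom. The difference between organs was tested on all 12 arrays, with 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes with an adjusted p under 0.05 were called. The number of arrays limits the precision.

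These tests, the alternatives and the gene lists were chosen before the data were examined, except for those stated next. After the data had been seen, each test was repeated with the sign of the replicate 2 ratios turned, because the replicates opposed each other in each comparison. Also chosen after seeing the data were fits without probes that match several loci, without the arrays of rounded values, and without spots whose local background exceeded 10 times the median of their array. A few such spots set the spread that normexp fits to the background. There were 5 on the shoot NaCl against control array of replicate 1, where the fitted spread was 124 in green and 58.7 in red (1.48 and 2.02 without them). There were 7 on the shoot Na2SO4 against control array of replicate 2, where it was 820 and 496 (1.01 and 1.46 without them). On the other arrays it lay between 0.836 and 6.78. The larger spread compressed the log2 ratios of these 2 arrays, whose standard deviation over the probes was 0.4 and 0.23, against 0.5 and 0.47 without the spots. The values of shoots against control and of the organ differences are therefore compressed in the fits that keep the spots.

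Genes named from the control comparisons are the 10 highest and 10 lowest that were called, had the same sign and a log2 ratio of size at least 1 in both replicates, kept their sign after adjustment for dye, and carried a description. For Na2SO4 against NaCl and for the organ differences they are the 5 highest and 5 lowest by the same rule, with the same sign in both replicates but no minimum size. For Na2SO4 against NaCl the difference of the control comparisons also had to share that sign. Where no gene passed, the 5 with the smallest unadjusted p each way stand in. A selection of these is given here, which is not always the most changed. Up to 4 members of each described list may be named, and each sulfate transporter.

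There were 26 gene lists, made by matching descriptions or by locus: LEA and dehydrin proteins, abscisic acid, sodium and potassium transport, chloride and anion channels, sulfate transporters, sulfate assimilation, glutathione S-transferases, antioxidant enzymes, class III peroxidases, osmolyte synthesis, aquaporins, photosynthesis, chlorophyll breakdown, heat shock proteins, ribosomal proteins, cell division and histones, cell wall, nitrogen, iron and metals, jasmonate, pathogenesis-related proteins, NAC, WRKY and AP2/ERF factors, fermentation and sucrose cleavage, and root markers. Descriptions matched by mistake were removed by hand. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. An estimated correlation and limma's fry were alternatives.

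The other alternatives were a dye term per organ or shared by both, a loop fit of the 3 comparisons, replicate number or slide as a term, the spread from all 12 arrays or from those of the comparison alone, no background correction or a normexp offset of 0, median centring, Aquantile normalization, the authors' log10 ratios turned to log2, other filters on dim or saturated probes, eBayes with trend and robust, a fold change of at least 2, all probes, and each replicate left out.

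The scripts were tested on simulated data with the design and spread of each comparison, in which 199 or 200 genes were changed. With replicate 2 turned, between 26.9% (shoot Na2SO4 against control) and 64.2% (root Na2SO4 against NaCl) of the genes changed by 1.5-fold were recovered. At 2-fold this was between 64.2% (shoot Na2SO4 against NaCl) and 92.5% (root Na2SO4 against NaCl), and at 4-fold between 89.4% and 98.5%. Between 2 and 17 unchanged genes were called per run. The shifted list was called in every run.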

Results

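Transcript levels were compared in shoots and roots of rice seedlings (cultivar IKP) after 48 h in 200 mM NaCl, in 100 mM Na2SO4 or without added salt. The salts supply the same concentration of sodium with different anions. The anion and total ion concentrations differ as well, so the kind of anion is not separated from osmotic strength. In each organ, NaCl was compared with the control, Na2SO4 with the control, and Na2SO4 with NaCl, each on 2 dual-channel arrays, which made 12 arrays in all. Of 43734 spots per array, between 25174 and 36691 were well above background in the green channel and between 21340 and 35862 in the red channel. The median green signal per array lay between 45.9 and 201.4 and the median red signal between 103.2 and 206.3. Saturation was limited to 2 green spots on 1 array. After filtering, 22787 genes were tested in shoots, 18796 in roots and 18309 in both organs. Genes of photosynthesis had median log2 intensities of 11.97 to 13.63 on the shoot arrays and 6.57 to 7.62 on the root arrays. Root marker genes had 7.29 to 9.15 on the shoot arrays and 9.47 to 10.43 on the root arrays. The 9.15 was that of Na2SO4 against control in replicate 2, an array with spots of extreme background. The other shoot arrays had at most 8.19. The number of arrays limits the precision.

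The replicates of each comparison ran in opposite directions as labelled. Across all probes that are not controls, before filtering, the log2 ratios of replicates 1 and 2 were correlated. In shoots the correlation was -0.884 for NaCl against control, -0.63 for Na2SO4 against control and -0.675 for Na2SO4 against NaCl. In roots it was -0.812, -0.861 and -0.737. The authors' own log ratios gave -0.756, -0.7 and -0.453 in shoots and -0.587, -0.672 and -0.441 in roots. Probes are not independent replicates, so these values describe the arrays and carry no test. A late embryogenesis abundant (LEA) protein of group 3 (Os05g0542500) had a log2 ratio of NaCl over control in shoots of 4.18 in replicate 1 and -4.45 in replicate 2. The labels put the treated RNA in the same dye on all arrays and do not settle which replicate follows its labels, so the direction of no change is settled here. Fits as labelled are reported last. The values before them come from a fit in which the ratios of replicate 2 were turned, which was chosen after seeing the data. Their signs are those of the replicate 1 labels, and "higher" and "lower" refer to these labels only. If the labels of replicate 2 hold instead, each sign is reversed and each count of higher genes becomes a count of lower genes.

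**Figure D1:**
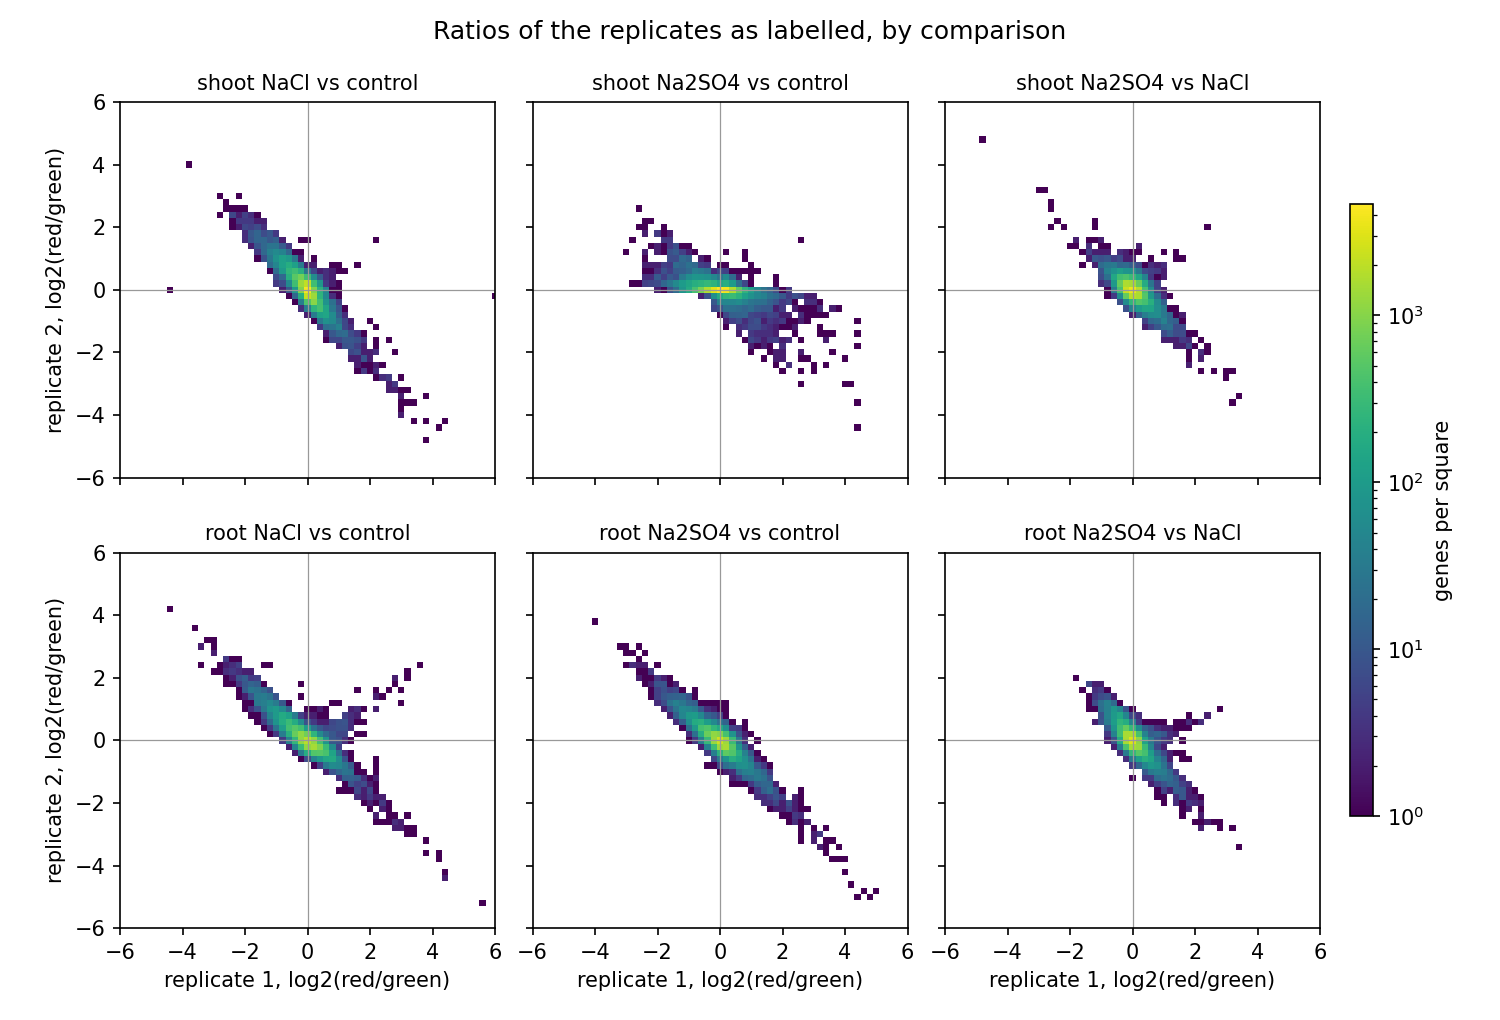
Log2 ratio of replicate 1 (horizontal) against replicate 2 (vertical) as labelled, for the 6 direct comparisons; the colour gives the number of genes per square on a log scale. The genes fall along a descending line in each panel, flatter for Na2SO4 against control in shoots. Over all probes that are not controls, which is more than the genes drawn, the correlations lay between -0.884 and -0.63.

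NaCl against control in shoots asked which transcripts differ in shoots under a chloride salt. The LEA gene Os05g0542500, of a family that protects cells against water loss, was higher in NaCl by a log2 of 4.31 ± 0.19 (SE, n = 2, adjusted p = 0.000256), a 19.9-fold difference; its probe lies on chromosome 5 at 27025822 to 27025881, in the coding sequence and 3' UTR. A lectin-C precursor (Os04g0493600, chromosome 4, 25192420 to 25192479) was higher by 3.27 ± 0.15 (adjusted p = 0.000305). Adenosine 5'-phosphosulfate (APS) reductase 2 (Os07g0509800, chromosome 7, 20070163 to 20070222), an enzyme that reduces activated sulfate, was lower with a log2 of -2.13 ± 0.17 (adjusted p = 0.00152). Also lower were the gamma chain of the chloroplast ATP synthase (Os07g0513000), with -2.02 ± 0.1 (adjusted p = 0.000308), and photosystem I subunit N (Os05g0242400), with -1.89 ± 0.1 (adjusted p = 0.00039). Cellulose synthase BoCesA7 (Os07g0252400, chromosome 7, 8533946 to 8534005, coding sequence and 3' UTR) had -1.8 ± 0.16, and WRKY transcription factor 45 (Os05g0322900) had -1.71 ± 0.16. In limma, 2869 genes differed, 1190 higher and 1679 lower. Median centring left fewer genes, most of them lower. Without spots of extreme background the count was 8045 (3596 higher and 4449 lower), and without replicate 1 or replicate 2 it was 252 or 111. With the slide as a term it was 87, and WRKY45 lost its call (adjusted p = 0.0728), while APS reductase 2 lost it without replicate 2 (adjusted p = 0.0504).

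Of the gene lists, photosynthesis was lower in NaCl in shoots, with 0 members higher, 6 lower and 4 not passing (0 higher and 7 lower adjusted over the list alone) and a mean log2 of -1.004 (camera adjusted p = 1.26e-05; adjusted p = 0.299 with an estimated correlation). A chlorophyll a-b binding protein (Os07g0577600) had -1.7 ± 0.08. The jasmonate list had 0 members higher, 5 lower and 2 not passing (0 and 5 adjusted over the list alone), and a mean of -0.609 (camera adjusted p = 0.00414; 0.299 with an estimated correlation). In it, a lipoxygenase (Os12g0559200), which starts the synthesis of oxylipins such as jasmonate, had -1.32 ± 0.18, and a ZIM protein (Os03g0402800) had -1.21 ± 0.15. Class III peroxidases had 0 members higher, 2 lower and 7 not passing (0 and 6 adjusted over the list alone) with a mean of -0.534 (0.0188; 0.552 with an estimated correlation). Cell wall genes had 1 higher, 3 lower and 13 not passing (1 and 5 adjusted over the list alone) with a mean of -0.35 (0.0425; 0.531 with an estimated correlation).

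Na2SO4 against control in shoots asked the same of the sulfate salt. The LEA gene Os05g0542500 was higher by 4.06 ± 0.19 (SE, n = 2, adjusted p = 0.000501). Its replicates had 4.45 and -3.66 as labelled, and the SE is the pooled one. An R1MYB1 protein (Os01g0192300, chromosome 1, 4970662 to 4970721, coding sequence and 3' UTR), of the MYB family of transcription factors, was higher by 2.38 ± 0.11 (adjusted p = 0.000501). Aldehyde dehydrogenase family 7 member A1 (Os09g0440300), of enzymes that oxidise reactive aldehydes, was higher by 2.33 ± 0.19, and NAC71 (Os11g0184900) by 1.85 ± 0.17. A 9-cis-epoxycarotenoid dioxygenase (NCED3, Os03g0645900, chromosome 3, 25772605 to 25772661), an enzyme of the committed step of abscisic acid synthesis, was higher by 1.8 ± 0.18 (adjusted p = 0.00423). Cellulose synthase BoCesA7 and APS reductase 2 were lower, with -2.11 ± 0.16 (adjusted p = 0.00143) and -2.11 ± 0.17 (adjusted p = 0.00192). Sedoheptulose-1,7-bisphosphatase (Os04g0234600), of the Calvin cycle, had -1.45 ± 0.08. In limma, 686 genes differed, 315 higher and 371 lower, against 8197 (3773 higher and 4424 lower) without spots of extreme background, 450 without replicate 1 and 6419 without replicate 2. These spots compressed the ratios of replicate 2, whose standard deviation over the probes was 0.23, against 0.47 without them. NCED3 (Os03g0645900) had 2.1 without them and the LEA gene Os05g0542500 4.44. In NaCl against control they compressed replicate 1 less, from 0.5 to 0.4. In Na2SO4 against control, median centring left fewer genes, most of them lower. With trend and robust eBayes, 0 genes passed (unadjusted p < 0.05 for 4393, smallest adjusted p = 0.171), and with the slide as a term 1 gene passed, so the named genes lost their calls in both, with the same signs.

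The photosynthesis list was lower in Na2SO4 in shoots as well, with 0 members higher, 5 lower and 5 not passing (0 and 5 adjusted over the list alone) and a mean of -0.605 (camera adjusted p = 0.000509; 0.407 with an estimated correlation). Abscisic acid genes were higher, with 2 members higher, 0 lower and 10 not passing (6 and 0 adjusted over the list alone) and a mean of 0.4, or 0.548 without spots of extreme background (0.00278; 0.407 with an estimated correlation). Class III peroxidases had 0 higher, 1 lower and 8 not passing (0 and 1 adjusted over the list alone) with a mean of -0.425, or -0.617 without those spots (0.00194; 0.451 with an estimated correlation). Ribosomal proteins had 0 higher, 4 lower and 20 not passing (1 and 5 adjusted over the list alone) with a mean of -0.196 (0.0111; 0.451 with an estimated correlation), among them a 50S protein L18 (Os03g0828100) with -1.1 ± 0.1. Cell wall genes had 0 higher, 2 lower and 15 not passing (0 and 2 adjusted over the list alone) with a mean of -0.326 (0.0361; 0.451 with an estimated correlation). Iron and metal genes had 0 higher, 0 lower and 6 not passing (1 and 0 adjusted over the list alone) with a mean of 0.252 (camera adjusted p = 0.0379, or 0.451 with an estimated correlation). When 1 array was left out, the cell wall mean ran from -0.47 to -0.183 and the iron mean from 0.151 to 0.353.

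Na2SO4 against NaCl in shoots asked which genes differ between the salts at the same sodium concentration. The design does not separate the kind of anion from its concentration or from osmotic strength. NCED3 (Os03g0645900) was higher in Na2SO4 by 3.33 ± 0.18 (SE, n = 2, adjusted p = 0.00118), the largest difference among named genes. A beta-carotene hydroxylase (Os03g0125100, chromosome 3, 1435421 to 1435480), which makes xanthophylls upstream of abscisic acid, was higher by 1.91 ± 0.15 (adjusted p = 0.00356). A plastid (P)ppGpp synthase (Os09g0442600) was higher by 1.88 ± 0.09 and the lipoxygenase Os12g0559200 by 1.41 ± 0.18. The lectin-C precursor was lower in Na2SO4, with -1.6 ± 0.15, as were a thaumatin-like pathogenesis-related protein (Os03g0661600), with -1.27 ± 0.17, and polyubiquitin (Os06g0606700), with -1.15 ± 0.1. In limma, 716 genes differed, 507 higher and 209 lower, or 70.8% higher. Without spots of extreme background the count was 2773 (1648 higher and 1125 lower, or 59.4%), and the authors' log ratios gave 2707 (1512 higher and 1195 lower, or 55.9%). Leaving out replicate 1 or replicate 2 left 15 or 10 genes, and NCED3 lost its call in both (adjusted p = 0.0541 and 0.0615). Median centring left 4 genes, 0 higher and 4 lower.

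In this comparison, the abscisic acid list had 2 members higher, 0 lower and 10 not passing (2 and 0 adjusted over the list alone) with a mean of 0.491 (camera adjusted p = 0.00689). Beside NCED3, a protein phosphatase 2C (Os05g0358500) had 0.72 ± 0.1. The list takes in proteins of this kind by their description alone, whether or not they act on abscisic acid. The jasmonate list had 2 higher, 0 lower and 5 not passing (3 and 0 adjusted over the list alone) with a mean of 0.51, and photosynthesis had 2 higher, 0 lower and 8 not passing (6 and 0 adjusted over the list alone) with a mean of 0.293, both with a camera adjusted p of 0.00689. When 1 array was left out, the photosynthesis mean ran from 0.16 to 0.426. NAC factors had 1 higher, 0 lower and 4 not passing (2 and 0 adjusted over the list alone) with a mean of 0.421 (0.0388). Each of these 4 lists had an adjusted p = 0.299 with an estimated correlation.

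NaCl against control in roots put the question of the chloride salt to the organ that meets it. The LEA gene Os05g0542500 was higher by 4.41 ± 0.11 (SE, n = 2, adjusted p = 1.26e-07). An ent-kaurene oxidase 1 (Os06g0569500, chromosome 6, 22899017 to 22899076, coding sequence), of diterpene synthesis, was higher by 2.64 ± 0.09 (adjusted p = 4.36e-07), and an RIR1b protein (Os10g0569800, chromosome 10, 23089164 to 23089223) by 2.48 ± 0.09. NCED3 was lower, with -2.3 ± 0.09 (adjusted p = 6.5e-07), and so was the beta-carotene hydroxylase Os03g0125100, with -2.09 ± 0.11. A metallothionein (Os01g0974200, chromosome 1, 44816483 to 44816542, coding sequence and 3' UTR), a protein that binds metal ions, had -2.29 ± 0.08 (adjusted p = 4.47e-07). CBL-interacting protein kinase 31 (Os03g0319400) had -2.01 ± 0.09, cellulose synthase BoCesA7 -1.97 ± 0.09 and tonoplast intrinsic protein2 (Os02g0658100), a water channel of the vacuole, -1.93 ± 0.11. In limma, 7637 genes differed, 3442 higher and 4195 lower, against 3745 without replicate 1. Median centring changed the split to 785 higher and 4314 lower.

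In roots in NaCl, class III peroxidases had 0 members higher, 7 lower and 2 not passing (0 and 7 adjusted over the list alone) with a mean of -0.724 (camera adjusted p = 0.00447; 0.471 with an estimated correlation). The abscisic acid list was lower there, with 1 member higher, 8 lower and 3 not passing (2 and 8 adjusted over the list alone) and a mean of -0.563 (0.0244; 0.471 with an estimated correlation).

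Na2SO4 against control in roots gave a higher LEA gene Os05g0542500, by 4.69 ± 0.11 (SE, n = 2, adjusted p = 5.54e-08), and a higher RIR1b gene, by 3.73 ± 0.09 (adjusted p = 7.46e-08). A phosphatidylethanolamine-binding protein (Os05g0468800) was higher by 3.04 ± 0.12 (adjusted p = 6.12e-07). Pyruvate dehydrogenase kinase 1 (Os07g0637300, chromosome 7, 27141666 to 27141725, coding sequence and 3' UTR), which switches off the entry of pyruvate into the citric acid cycle, was higher by 2.16 ± 0.11 (adjusted p = 1.97e-06). Cellulose synthase BoCesA7 was lower, with -2.18 ± 0.09 (adjusted p = 9.62e-07). Pleiotropic drug resistance protein 3 (Os01g0609300) had -1.68 ± 0.11, a protein phosphatase 2C (Os02g0471500) -1.52 ± 0.11 and phosphate transporter 6 (Os10g0444700) -1.44 ± 0.12. In limma, 5917 genes differed, 2728 higher and 3189 lower, against 2990 without replicate 1 and 3658 without replicate 2. Median centring changed the split to 842 higher and 3475 lower, as it moved the median log2 ratio of all genes from 0.009 to -0.1. Class III peroxidases were the one list that passed, with 0 higher, 6 lower and 3 not passing (0 and 6 adjusted over the list alone) and a mean of -0.575 (camera adjusted p = 0.00577; 0.685 with an estimated correlation).

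Na2SO4 against NaCl in roots showed a higher UDP-glucose-4-epimerase (Os05g0595100), by 2.29 ± 0.19 (SE, n = 2, adjusted p = 9.96e-05). A tonoplast water channel (Os03g0146100, chromosome 3, 2561857 to 2561916, coding sequence and 3' UTR) was higher in Na2SO4 by 2.01 ± 0.1 (adjusted p = 9.03e-06), and NCED3 by 1.79 ± 0.09 (adjusted p = 1.12e-05). Ferritin 1 (Os11g0106700), which stores iron, was higher by 1.71 ± 0.14 and a trehalose-6-phosphate synthase (Os02g0790500) by 1.7 ± 0.11. A beta-galactosidase (Os06g0573600) was lower, with -1.61 ± 0.19, and a kinesin (Os09g0528000) had -1.49 ± 0.17. In limma, 4096 genes differed, 2023 higher and 2073 lower, against 2338 without replicate 1 and 1118 without replicate 2. Median centring left 614 (474 higher and 140 lower), and the water channel lost its call with 1.28 (adjusted p = 0.129), as did the beta-galactosidase (0.0618) and the kinesin (0.0594).

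The abscisic acid list was higher in Na2SO4 than in NaCl in roots, with 5 members higher, 0 lower and 7 not passing (5 and 0 adjusted over the list alone) and a mean of 0.378 (camera adjusted p = 0.0154). In this list an abscisic stress ripening protein 1 (Os02g0543000) had 0.85 ± 0.09. Photosynthesis had 0 higher, 3 lower and 4 not passing (0 and 3 adjusted over the list alone) with a mean of -0.402 (0.0154). In it, a locus described as similar to photosystem II protein D1 (Os04g0473150) had -0.95 ± 0.09. AP2/ERF factors had 2 higher, 0 lower and 5 not passing (2 and 0 adjusted over the list alone) with a mean of 0.35 (0.0182). These 3 lists had an adjusted p = 0.275 with an estimated correlation.

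**Figure D2:**
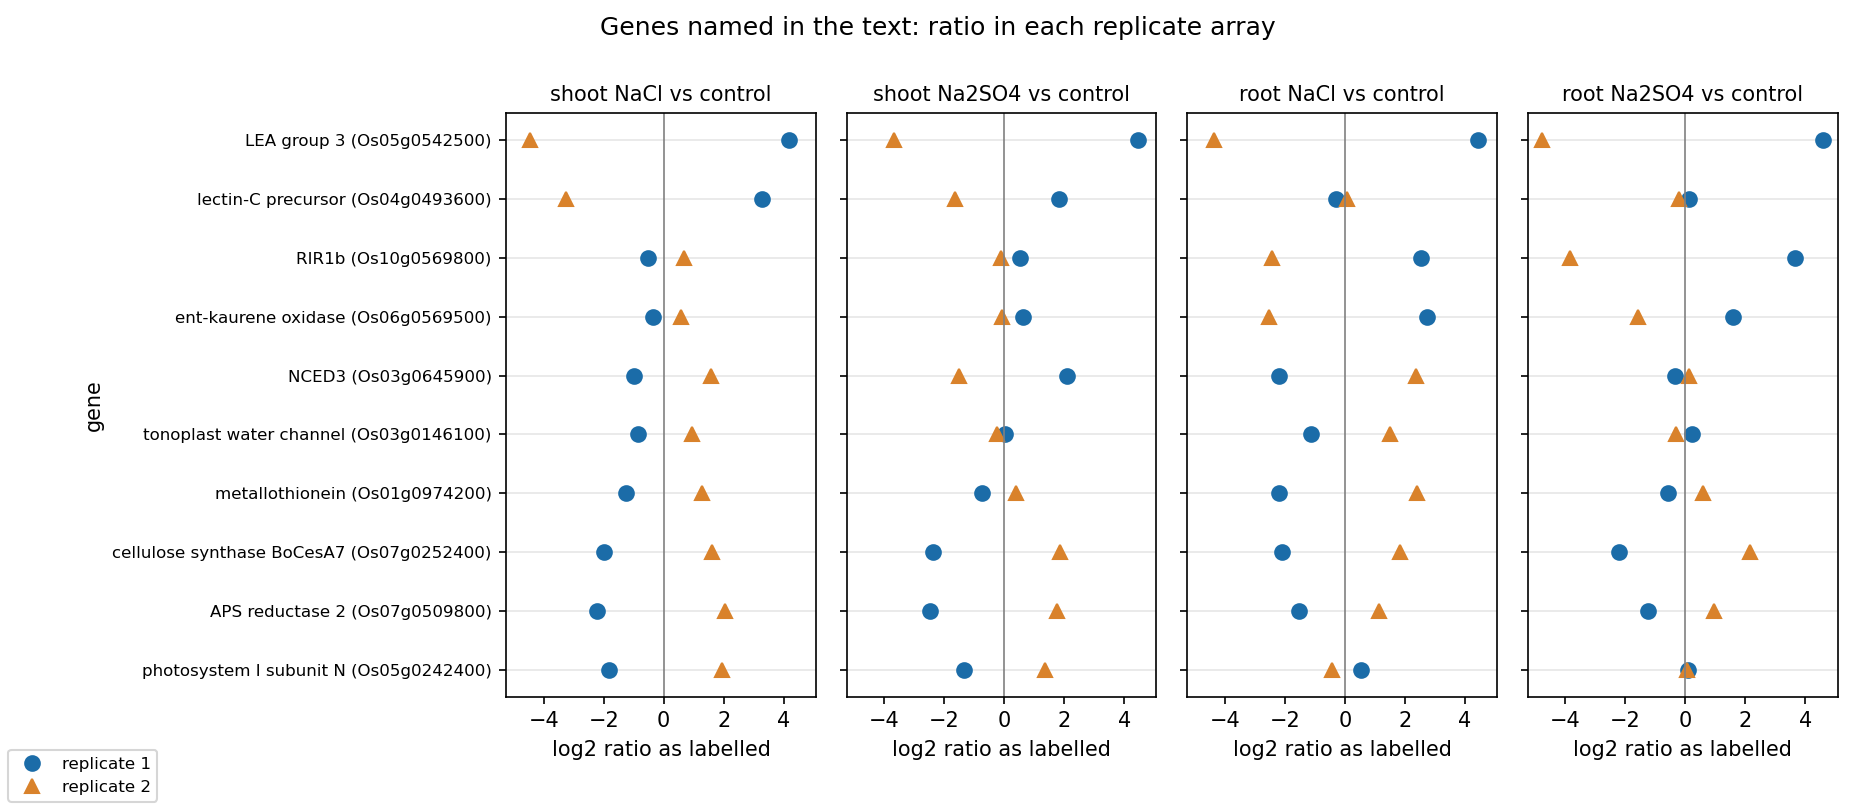
Log2 ratio as labelled (treated over control) of 10 genes in the 4 control comparisons; each point is 1 array. Where a gene's ratio is far from 0, replicates 1 and 2 have opposite signs, as for the LEA gene with 4.18 and -4.45 in shoots in NaCl.

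The difference between organs asked whether roots and shoots respond alike. In NaCl, the log2 ratio to control was higher in roots than in shoots by 3.11 ± 0.19 for ent-kaurene oxidase 1 (SE, n = 2, adjusted p = 4.76e-06) and by 3.08 ± 0.15 for RIR1b. For photosystem I subunit N (Os05g0242400) it was higher by 2.39 ± 0.12 (adjusted p = 1.94e-06), with -1.89 in shoots and 0.49 in roots, so the larger change was in shoots. The log2 ratio of the lectin-C precursor was lower in roots, with -3.45 ± 0.18 (adjusted p = 2.06e-06), as was that of glucose-1-phosphate adenylyltransferase (Os09g0298200, chromosome 9, 7863593 to 7863652, coding sequence and 3' UTR), an enzyme of starch synthesis, with -2.62 ± 0.14. Phosphoenolpyruvate carboxylase 1 (Os02g0244700) had -2.15 ± 0.19. In limma, 3285 genes differed between the organs in NaCl, 1375 higher and 1910 lower. The count was 5104 (2200 higher and 2904 lower) without spots of extreme background, 2187 and 1365 without shoot replicates 1 and 2, and 1577 and 2150 without root replicates 1 and 2. Photosynthesis had 5 members higher, 0 lower and 2 not passing (5 and 0 adjusted over the list alone) with a mean of 1.135 and a camera adjusted p of 3.01e-05. It was the only list of any comparison whose call held with an estimated correlation (adjusted p = 0.0387). The abscisic acid list had 0 higher, 6 lower and 6 not passing (0 and 6 adjusted over the list alone) with a mean of -0.556 (0.0031; 0.184 with an estimated correlation).

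In Na2SO4, the log2 ratio to control was higher in roots by 3.41 ± 0.15 for RIR1b (SE, n = 2, adjusted p = 1.24e-06) and by 2.05 ± 0.13 for an ethylene receptor-like protein 1 (Os04g0169100). It was lower in roots for NAC71, with -2.54 ± 0.21 (adjusted p = 4.08e-05), for NCED3 (Os03g0645900), with -2.02 ± 0.22, or -2.33 without spots of extreme background (adjusted p = 0.000212), and for phosphoenolpyruvate carboxylase 1, with -1.97 ± 0.19. In limma, 1797 genes differed between the organs in Na2SO4, 794 higher and 1003 lower. The count was 4278 (1857 higher and 2421 lower) without spots of extreme background, 3251 without shoot replicate 2, 827 without root replicate 1 and 1054 without root replicate 2. The abscisic acid list had 0 higher, 3 lower and 9 not passing (0 and 4 adjusted over the list alone) with a mean of -0.51, or -0.657 without those spots (camera adjusted p = 0.0103; 0.277 with an estimated correlation). Photosynthesis did not pass, with 4 higher, 1 lower and 2 not passing (4 and 2 adjusted over the list alone) and a mean of 0.322 (0.0763).

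The responses to both salts were compared within each organ. In roots 1560 genes were higher in both salts and 2590 lower in both, against 500 and 712 if the calls were independent, and 170 were called in opposite directions. In shoots 213 were higher in both and 333 lower in both, against 16 and 27, and 16 were opposite. Without spots of extreme background the shoot counts were 2296 and 3170, against 595 and 864, with 183 opposite. Across genes, the responses correlated with 0.76 in roots and 0.78 in shoots. Noise shared through the common control, simulated 20 times for unchanged genes, gave 0.49 and 0.5. A shared control gives such a value whatever the size of the noise, so it does not measure the shared part. The covariance does take in the size, with 0.162 in roots and 0.112 in shoots, against 0.00763 and 0.0121 simulated. Responses were also solved, together with a dye term, from the arrays of each replicate number in an organ. The solved NaCl response was paired with the solved Na2SO4 response of the other replicate number, with replicate 2 turned. This gave 0.583 and 0.621 in roots and -0.289 and 0.293 in shoots (0.726 and 0.73 without spots of extreme background). The direct arrays against control were paired in the same way over all probes that are not controls. As labelled they correlated with -0.632 and -0.71 in roots and -0.608 and -0.718 in shoots. With replicate 2 turned, these signs are reversed.

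Genes of ion and water transport were followed because the salts differ in their anion. The sodium transporter locus Os06g0701700, fixed by its identifier, was lower in NaCl in shoots, with -0.92 ± 0.12 (n = 2, adjusted p = 0.00577), and higher in Na2SO4 in roots, by 0.61 ± 0.1 (adjusted p = 0.00184). Os07g0666900, of the same list, was higher in roots by 1.06 ± 0.1 in NaCl and 1.28 ± 0.1 in Na2SO4. Potassium transporter 7 (Os07g0669650) was lower in roots in NaCl, with -1.09 ± 0.09 (adjusted p = 2.56e-05). As a list, sodium and potassium transport passed in no comparison. It came nearest in shoots in Na2SO4 against NaCl, with 0 members higher, 0 lower and 12 not passing (2 and 0 adjusted over the list alone; mean 0.218, camera adjusted p = 0.0678), and passed there without spots of extreme background (0.0454). In NaCl in shoots it had 0 members higher, 3 lower and 9 not passing (1 and 4 adjusted over the list alone; mean -0.205, camera adjusted p = 0.0994). Of 3 sulfate transporters 1 was measured, sulfate transporter 4.1 (Os09g0240500), with 0.62 ± 0.18 in roots in Na2SO4 (adjusted p = 0.0309) and -0.65 in shoots in NaCl (adjusted p = 0.0548). Aquaporins had 5 measured members in shoots, with 0 higher, 1 lower and 4 not passing in NaCl (0 and 2 adjusted over the list alone; mean -0.231, camera adjusted p = 0.31), and 4 in roots, too few to test, among them NIP1-1 (Os02g0232900) with 1.07 in NaCl (adjusted p = 8.25e-05).

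Several lists were too small for a test. The list of chloride and anion channels had 0 members and that of LEA proteins 1, Os05g0542500. Both lists take in described genes only, so the array may measure other genes of these families that are not listed. Sulfate assimilation had 2 serine acetyltransferases. Os02g0202700 was higher in roots in NaCl by 0.8 (adjusted p = 0.00108) and Os05g0533500 was lower in shoots in NaCl, with -0.44 (adjusted p = 0.0268). APS reductase 2 (Os07g0509800), which reduces activated sulfate, is missing from this list because its description did not match the terms searched. It had -2.13 in NaCl and -2.11 in Na2SO4 in shoots, a larger change than these members had. Of the glutathione S-transferases, GSTU1 (Os03g0785900) had -0.39 in roots in Na2SO4 (adjusted p = 0.0242). Among antioxidant enzymes, a thylakoid-bound ascorbate peroxidase (Os04g0434800) had -0.65 in NaCl and -0.69 in Na2SO4 in roots, while ascorbate peroxidase 8 (Os02g0553200) had 0.52 and 0.6. In osmolyte synthesis, the trehalose-6-phosphate synthase Os02g0790500 had -1.54 ± 0.12 in roots in NaCl (adjusted p = 1.6e-05). In chlorophyll breakdown, pheophorbide a oxygenase (Os03g0805600) had -0.64 in shoots in NaCl (adjusted p = 0.00735). In nitrogen metabolism, the chloroplastic glutamine synthetase (Os04g0659100) had -1.26 in NaCl and -0.96 in Na2SO4 in shoots. The root marker Os02g0662000 had -3.06 ± 0.12 in NaCl and -3.9 ± 0.12 in Na2SO4 in roots.

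Other tested lists passed camera in no comparison. Pathogenesis-related proteins came nearest of these, with 6 members higher, 1 lower and 5 not passing in roots in NaCl (6 and 1 adjusted over the list alone; mean 0.27, camera adjusted p = 0.0714). Heat shock proteins had 7 higher, 4 lower and 8 not passing there (7 and 4 adjusted over the list alone; mean 0.076, or -0.026 with median centring; 0.725) and 1 higher, 4 lower and 17 not passing in shoots (1 and 4 adjusted over the list alone; mean -0.166, 0.0994). They passed without spots of extreme background in shoots in Na2SO4 (mean -0.287, 0.037) and for the organ difference in NaCl (mean 0.214, 0.0461). WRKY factors had 0 higher, 3 lower and 9 not passing in shoots in NaCl (2 and 3 adjusted over the list alone), with a mean of -0.136, or 0.03 with the authors' log ratios, and a median of 0.096 (0.998). Cell division genes and histones had 1 higher, 0 lower and 9 not passing for the organ difference in Na2SO4 (1 and 0 adjusted over the list alone; mean 0.122, 0.335). Fermentation and sucrose cleavage had 0 higher, 0 lower and 6 not passing in shoots in Na2SO4 against NaCl (0 and 0 adjusted over the list alone; mean 0.245, 0.0974). Of the 118 list tests with replicate 2 turned, 23 passed, and mean, median and test had the same sign in each of these. Mean and median differed in sign in 31 of the others, such as NAC factors in shoots in Na2SO4 (0.347 and -0.075), and mean and test in 12, such as the abscisic acid list in shoots in NaCl (mean -0.016, median 0.07, test upward).

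**Figure D3:**
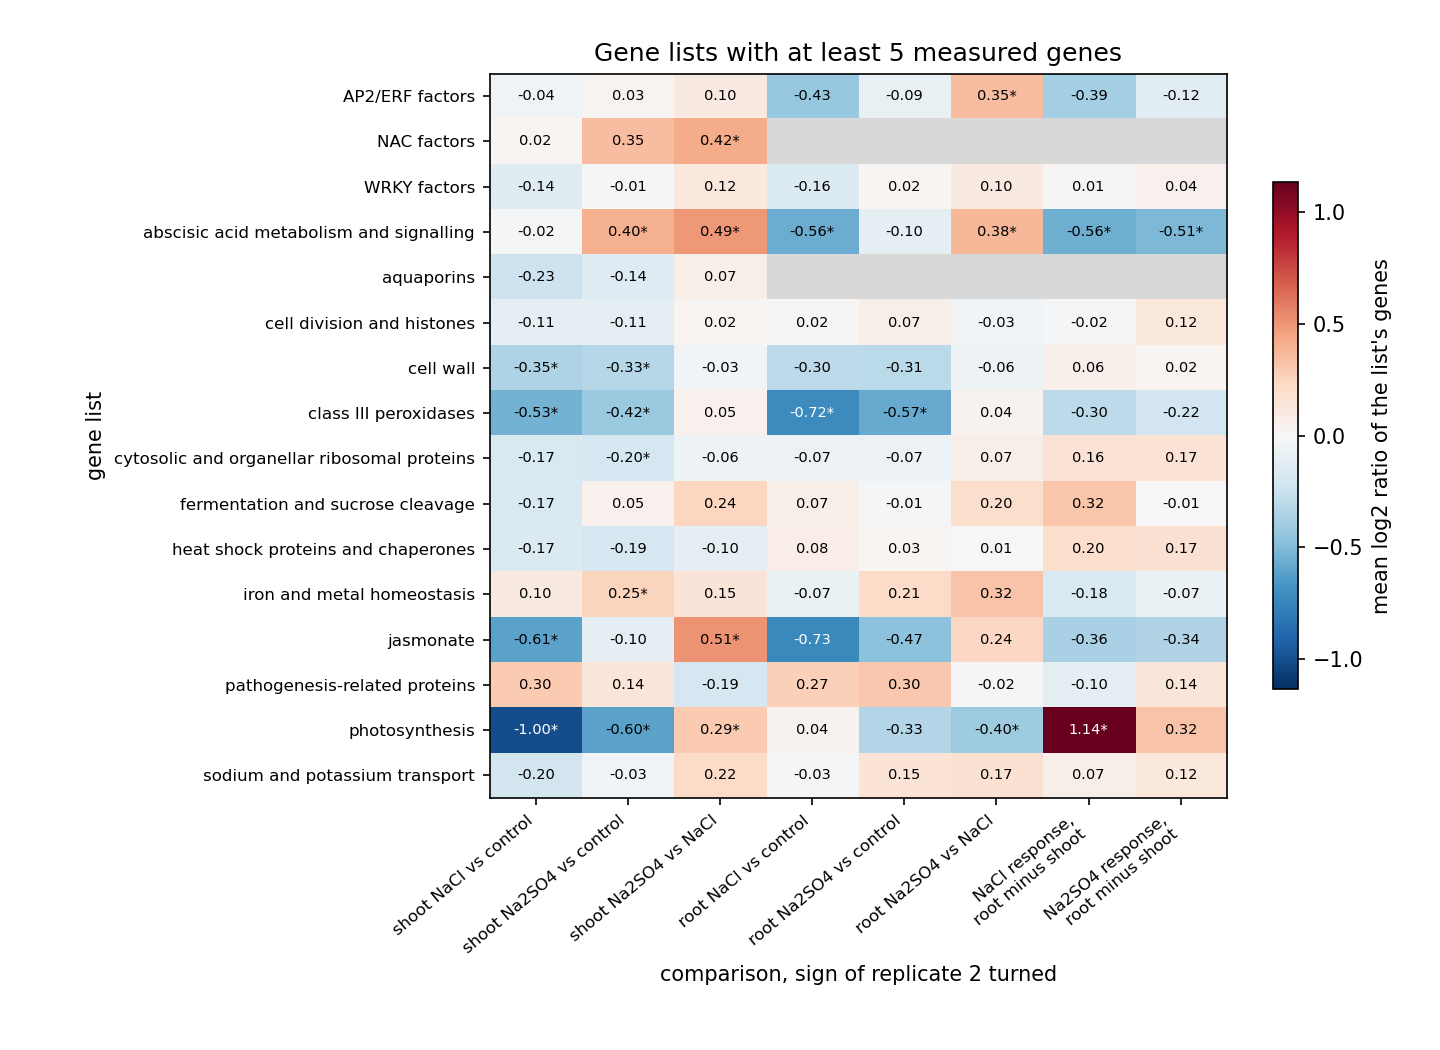
Mean log2 ratio of the members of each gene list in the 6 direct comparisons and the organ differences, with replicate 2 turned and signs of the replicate 1 labels; an asterisk marks a camera adjusted p under 0.05 and grey marks fewer than 5 measured members. The lowest mean is that of photosynthesis in shoots in NaCl (-1.004) and the highest its organ difference in NaCl (1.135).

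With the labels taken as they stand, limma called 0 genes in each of the 8 comparisons and organ differences, and the smallest adjusted p was 1 in each. Unadjusted p < 0.05 was reached by 45, 42 and 123 genes in shoots for NaCl against control, Na2SO4 against control and Na2SO4 against NaCl, by 109, 2 and 29 in roots, and by 71 and 1 for the organ differences in NaCl and Na2SO4. A neutral/alkaline invertase (Os04g0432400), which splits sucrose, had the smallest p among described genes in roots in NaCl, with 2.58 ± 0.48 (limma, unadjusted p = 0.00302, adjusted p = 1; replicates 3.14 and 2.01), but -1.07 after adjustment for dye. The locus described as similar to photosystem II protein D1 (Os04g0473150) had 0.9 ± 0.21 in shoots in Na2SO4 (limma, unadjusted p = 0.00835, adjusted p = 1). Of 118 list tests as labelled, 1 passed: fermentation and sucrose cleavage for the organ difference in NaCl, with 0 higher, 0 lower and 5 not passing (1 and 0 adjusted over the list alone), a mean of 0.495 and a median of 0.053 (camera adjusted p = 0.033; 0.561 with an estimated correlation). The invertase had 2.59 ± 0.54 there, and the other 4 members lay between -0.216 and 0.12. The same list had a mean of 0.319 with replicate 2 turned (camera adjusted p = 0.456).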

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

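The tests of the organ differences were chosen in advance for the labels as they stand; those with replicate 2 turned, and the leaving out of spots of extreme background, were chosen only after the result was seen. Each result here is a difference between roots and shoots in the response to the same salt, found by testing the difference itself on all 12 arrays. With replicate 2 turned, 3285 genes responded differently to NaCl in roots and shoots and 1797 to Na2SO4. The photosynthesis list had a mean difference, roots minus shoots, of 1.14 in NaCl, and the abscisic acid list had -0.56 in NaCl and -0.51 in Na2SO4. As labelled, the fermentation and sucrose cleavage list had a mean difference of 0.5 in NaCl.

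The difference in photosynthesis went with a list mean of -1.004 in shoots in NaCl, against 0.043 in roots (-0.086 there with median centring). Fewer members were measured in roots, so these means cover different genes. The difference itself covers only those measured in both organs. These genes had median log2 intensities of at most 7.62 on the root arrays and at least 11.97 on the shoot arrays, so a change in roots is measured on a weak signal. The call held under each alternative run, including an estimated correlation between members (adjusted p = 0.0387). A response of green tissue that roots lack may explain it, as may the weak root signal; neither was tested, and the organ is the only biological factor the design offers.

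The differences in the abscisic acid list included NCED3, with -1 ± 0.22 in NaCl and -2.02 ± 0.22 in Na2SO4, and a protein phosphatase 2C (Os02g0471500), with -1.43 ± 0.17 and -1.37. Neither held with an estimated correlation (adjusted p = 0.184 and 0.277), and that in Na2SO4 missed the threshold without shoot replicate 1 (-0.385, adjusted p = 0.0501). No technical explanation was tested for it.

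The fermentation call as labelled did not hold with an estimated correlation. In it, the invertase Os04g0432400 had 2.59 and the other members lay between -0.216 and 0.12. The list mean reversed after adjustment for dye (-0.172), so a dye effect of that probe may underlie it. This gene had more red than green signal in both replicates of NaCl against control in roots, whereas 712 genes with a log2 ratio of at least 1 in size in both replicates changed sign.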

How the results depend on the processing

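Tests with replicate 2 turned, and those without spots of extreme background, without the arrays of rounded values and without probes of several loci, were chosen only after the result was seen. Unless stated, counts are of genes with replicate 2 turned, given for shoots and then roots in the order NaCl against control, Na2SO4 against control and Na2SO4 against NaCl, and then for the organ differences in NaCl and Na2SO4. Where no cause is given, the cause was not tested.

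As labelled, 0 genes passed in limma in each comparison under each alternative, except for 1 gene in the organ difference in NaCl without shoot replicate 2 (range 0 to 1 when 1 array was left out). The counts at an unadjusted p under 0.05 are in the report. With replicate 2 turned the counts became 2869, 686, 716, 7637, 5917, 4096, 3285 and 1797. None of the 120 genes named with replicate 2 turned changed sign under an alternative. They were chosen for the same sign in both replicates and after adjustment for dye. Leaving out a replicate or adding a dye term could therefore hardly turn them, and shows no stability. A gene named in several comparisons is counted in each. As labelled, 63 of the values of the 80 named genes changed sign, none past the threshold.

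Terms in the fit moved the counts most in shoots. With a dye term per organ they were 8051, 6305 and 4466 in shoots, 9400 and 7459 for Na2SO4 against control and against NaCl in roots, and 7904 and 5018 for the organs. With a dye term shared by the organs they were 9606, 8708 and 5939, then 8942 and 6882, and 7941 and 5039. The loop fit gave 6463, 4106 and 2659 in shoots and 6188 and 3768 for the organs. With the slide as a term, which leaves 1 residual degree of freedom per organ, shoots gave 87, 1 and 3, and Na2SO4 against NaCl in roots 6554. With the replicate number as a term, Na2SO4 against NaCl gave 1094 in shoots and 6306 in roots, and the organ difference in NaCl 4994. The labels tie replicate numbers of different comparisons by number only; the replicate differences of the comparisons correlated across genes between -0.033 and 0.526 with replicate 2 turned. One spread from all 12 arrays gave 5331, 2041 and 2075 in shoots, and the arrays of the comparison alone gave 7271, 112 and 3079 in shoots and 496 for the organ difference in Na2SO4. The fit with trend and robust gave 4687, 0 and 2088 in shoots.

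Without the spots of extreme background, which inflate the fitted background spread, shoots gave 8045, 8197 and 2773 and the organs 5104 and 4278. Without background correction shoots gave 8491, 8433 and 3000 and the organs 5504 and 4626. An offset of 0 gave 1755, 390 and 435 in shoots. The authors' log ratios gave 7923, 7139 and 2707 in shoots and 3264 for the organ difference in Na2SO4, and the values in the deposited table gave counts of 7920, 7145, 2708 and 3264. Median centring gave 666 (112 higher and 554 lower), 272 (29 and 243) and 4 (0 and 4) in shoots, 614 (474 and 140) for Na2SO4 against NaCl in roots, and 1519 (443 and 1076) and 817 (331 and 486) for the organs. Without the arrays of rounded values the counts were 6290, 6419 and 2658 in shoots and 2990 for Na2SO4 against control in roots, with fewer arrays. In shoots, the array of rounded values left out also holds spots of extreme background, so that fit changes both things together. A fold change of at least 2, a stricter rule by construction, left 726, 328, 200, 890, 805, 344, 878 and 586. All probes, a larger number of tests, gave 4321 and 1077 in shoots against control. Under Aquantile normalization, both filters on dim probes, the filter on saturated probes and without probes of several loci, each count stayed within 1.5 times.

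Leaving out 1 array, which leaves a lone array assumed to vary like the others, gave 111 to 252, 450 to 6419 and 10 to 15 genes in shoots, 3745 to 6022, 2990 to 3658 and 1118 to 2338 in roots, and 1365 to 2187 and 827 to 3251 for the organs.

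Among the lists with replicate 2 turned, 125 means changed sign under an alternative, none of them of a list with a call. With an estimated correlation, 22 of 23 calls ended at unchanged means: in shoots in NaCl photosynthesis (-1.004), jasmonate (-0.609), peroxidases (-0.534) and cell wall (-0.35), in shoots in Na2SO4 photosynthesis (-0.605), peroxidases (-0.425), abscisic acid (0.4), cell wall (-0.326), iron (0.252) and ribosomal proteins (-0.196), in shoots in Na2SO4 against NaCl jasmonate (0.51), abscisic acid (0.491), NAC (0.421) and photosynthesis (0.293), in roots peroxidases (-0.724 in NaCl and -0.575 in Na2SO4), abscisic acid (-0.563 in NaCl and 0.378 in Na2SO4 against NaCl), photosynthesis (-0.402) and AP2/ERF (0.35), and between organs abscisic acid (-0.556 and -0.51). With fry the calls of cell wall (-0.326), peroxidases (-0.425) and iron (0.252) in shoots in Na2SO4 ended.

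The cell wall list in shoots in NaCl lost its call with a dye term (-0.331, adjusted p = 0.082, or 0.0633 when shared), in the loop fit (-0.331), with the slide (-0.35, 0.0505), without a filter (-0.287) and with a filter on both channels (-0.349). The peroxidases there lost it without a filter (-0.384). In shoots in Na2SO4, the cell wall list lost its call with median centring (-0.423), without a filter (-0.263), with a filter on both channels (-0.347) and without rounded arrays (-0.47), where ribosomal proteins (-0.237) lost theirs too. The iron list there lost it with the slide (0.241), no background correction (0.336), median centring (0.139), the authors' log ratios and the deposited table (0.591), without spots of extreme background (0.323) and without rounded arrays (0.353).

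In Na2SO4 against NaCl in shoots, the NAC list lost its call in the loop fit (0.388), without background correction (0.424), with median centring (0.418), with the authors' log ratios and the deposited table (0.626), without a filter (0.291), without spots of extreme background (0.421) and without rounded arrays (0.421, adjusted p = 0.0518). Photosynthesis there lost it with median centring (0.32) and with the authors' log ratios and the deposited table (0.279). In roots in NaCl, the abscisic acid list lost it without background correction (-0.557), with an offset of 0 (-0.592), with median centring (-0.732), with the authors' log ratios and the deposited table (-0.621) and with a filter on both channels (-0.632). Peroxidases in roots in Na2SO4 lost it with median centring (-0.687). In Na2SO4 against NaCl in roots, calls ended for AP2/ERF and photosynthesis with a shared dye term (0.347 and -0.392) and with 1 spread from all arrays (0.35 and -0.402), and for both and abscisic acid with the authors' log ratios and the deposited table (0.633, -0.59 and 0.48). The abscisic acid list also lost it there with median centring (0.322).

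When 1 array was left out, calls ended for lists with these ranges of means: cell wall -0.399 to -0.301 in shoots in NaCl and -0.47 to -0.183 in Na2SO4; ribosomal proteins -0.237 to -0.155 and iron 0.151 to 0.353 in Na2SO4; NAC 0.405 to 0.436 and photosynthesis 0.16 to 0.426 in Na2SO4 against NaCl. In roots they were abscisic acid -0.564 to -0.561 in NaCl and AP2/ERF 0.321 to 0.378 in Na2SO4 against NaCl, and between organs abscisic acid -0.634 to -0.385 in Na2SO4.

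As labelled, the fermentation call in the organ difference in NaCl reversed with a dye term (-0.172, adjusted p = 0.803). It ended with a shared dye term and in the loop fit (0.273), with median centring (0.414), without a filter (0.392), with fry, with an estimated correlation and without rounded arrays (0.495), and ranged from 0.244 to 0.746 when 1 array was left out. Lists that did not pass as labelled passed with the other sign with the slide as a term, in shoots: peroxidases 0.328 in Na2SO4 against NaCl, and jasmonate -0.427 and photosynthesis -0.393 in NaCl. Others did so when 1 array was left out, as the replicates oppose each other. In shoots in NaCl these were peroxidases (-0.5 to 0.568), jasmonate (-0.577 to 0.641) and photosynthesis (-0.933 to 1.074), in shoots in Na2SO4 abscisic acid (-0.276 to 0.525), ribosomal proteins (-0.237 to 0.155) and iron (-0.151 to 0.353), and between organs photosynthesis (-1.205 to 1.014) in NaCl and ribosomal proteins (-0.213 to 0.274) and pathogenesis-related proteins (-0.341 to 0.323) in Na2SO4.

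Of the 120 genes named with replicate 2 turned, 37 lost their call with the slide as a term, 29 with median centring, 20 with trend and robust, 16 without replicate 1 and 20 without replicate 2. With the arrays of the comparison alone 3 lost it, and 1 each with the replicate number, without a filter and with an offset of 0. Lists that did not pass before passed with fry in 33 tests, without spots of extreme background in 3 (heat shock proteins in shoots in Na2SO4, with -0.287, and between organs in NaCl, with 0.214, and sodium and potassium transport in shoots in Na2SO4 against NaCl, with 0.218), and with the slide and without a filter in 2 each. As labelled, such lists that kept their sign were at most 5 under any alternative, and at most 3 passed with the other sign. Signal over background limits the dim probes: green signal was well above background in as few as 25174 spots and red in as few as 21340.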

Other observations

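The tests of opposite dyes, of channel backgrounds and of a slide effect, the fits with replicate 2 turned and without spots of extreme background, and the choice of genes in the first and last paragraphs were made only after the result was seen; the remaining tests were fixed before their results.

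NCED3 (Os03g0645900) differed between the salts in both organs, in the direction of the replicate 1 labels. It was lower in NaCl in shoots, with -1.29 ± 0.18 (n = 2, limma adjusted p = 0.00815), and in roots, with -2.3 ± 0.09, whereas in Na2SO4 it was higher in shoots by 1.8 ± 0.18 and had -0.23 ± 0.09 in roots (adjusted p = 0.091). The trehalose-6-phosphate synthase Os02g0790500 had -1.54 in NaCl and -0.07 in Na2SO4 in roots, and -0.43 and 0.74 in shoots. Cellulose synthase BoCesA7 (Os07g0252400) did not separate the organs at this precision, with a difference between them of -0.17 ± 0.19 in NaCl and -0.07 ± 0.19 in Na2SO4, and had -0.26 ± 0.16 in shoots and -0.47 ± 0.09 in roots in Na2SO4 against NaCl.

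The opposition of the replicates was weighed against 4 explanations. Exchanged channels in the scanner files would exchange the background levels, but the median red background lay between 71 and 76 on the replicate 2 arrays and the median green background between 19.5 and 30 on those of replicate 1. Spike-in controls, chosen beforehand for this question, left it open. Their mean ratios correlated between replicates with 0.909 over 10 kinds, but with 0.091 over the 8 without the 2 of largest ratio, and 6 kinds changed sign. The lowest correlation between 2 arrays was 0.117, and these spots were dim, with a median log2 signal of 5.7. Plants that responded in opposite directions would change the mean intensity of both channels against the response. In the comparisons with control the slope would be near -1, but the lowest of the 6 slopes, in shoots in Na2SO4 against control, was -0.029. In Na2SO4 against NaCl both RNAs would change, so the slopes there (0.047 in shoots and 0.026 in roots) cannot decide. A slide effect would align the arrays of 1 slide, but the root replicate 1 and shoot replicate 2 arrays of Na2SO4 against control on 1 slide correlated with -0.311, against 0.454 and 0.39 for arrays of 1 replicate number on different slides. Labelling in opposite dyes in 1 replicate number would keep the dye term and turn the responses. In roots the dye term correlated between replicates with 0.202, the NaCl response with -0.897 and the Na2SO4 response with -0.633. In shoots the values were 0.638, -0.627 and 0.372, so the Na2SO4 response solved from the 3 arrays did not turn there; without spots of extreme background, which compress the ratios of 2 shoot arrays, they were 0.142, -0.922 and -0.824. The values in roots, and in shoots without those spots, are consistent with a dye swap or with exchanged RNA tubes, as both give the same data.

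Which replicate follows its labels was tested with 9 loci known beforehand to rise under salt or abscisic acid. Their median log2 ratio in the 4 control comparisons lay between 1.87 and 3.47 in replicate 1, whose lowest was 1.87 in shoots in NaCl, and between -3.51 and -1.57 in replicate 2. Replicate 1 may therefore follow its labels and replicate 2 be turned, but the test rests on knowledge from outside these data and the labels do not settle it. Exceptions were present, as 6 of the 9 loci were above 0 in replicate 1 in roots in each salt and 3 in replicate 2 in roots in NaCl. Of the 9, Os11g0453900, Os11g0454000, Os11g0454200 and Os11g0454300 have neighbouring identifiers on chromosome 11, so they may not count as separate loci. In roots in replicate 1 these had 5.55, 1.64, 3.78 and 4.33 in NaCl and 4.49, 2.62, 3.95 and 4.77 in Na2SO4. The others had 2.81, -2.21, -0.19, 4.45 and -2.11 in NaCl and 3.47, -0.35, -0.34, 4.6 and -0.31 in Na2SO4. The root medians of replicate 1 therefore lean on the chromosome 11 loci. NCED3 itself was 1 of the 9 loci and ran against the premise in NaCl, with -1 in shoots and -2.21 in roots in replicate 1, against 1.59 and 2.38 in replicate 2. In Na2SO4 in shoots it had 2.09 and -1.5.

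Few genes held their sign in both replicates as labelled. Of those with a log2 ratio of at least 1 in size in both replicates, 18 had more red signal and 0 more green in both replicates of NaCl against control in roots, and 712 changed sign; over the other comparisons the genes with more red signal in both numbered 1, 1 and 3 in shoots and 0 and 1 in roots. The 18 genes, of which 1 carried a description (the invertase Os04g0432400), had a median log2 ratio above 0 on each of the other 10 arrays, from 0.07 to 1.83.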
